A study of Mus musculus with 4 samples.

How the data were processed

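Libraries of RNA from spheres of mouse lung tumour cells were sequenced, 2 from spheres given PBS vehicle and 2 from spheres given 10 µM cisplatin for 36 h. Per the labels' protocols, total RNA was extracted with TRIzol, cleaned and treated with DNase, and made into strand-specific libraries depleted of ribosomal RNA. Per the submitters' processing notes, bcl2fastq, Trimmomatic 0.38, STAR 2.5.1b and edgeR were used with the build mm10. The gene annotation, the counting rule with its strand setting, the filter on low genes and the scaling method are not given in the sources used here. Without a stated strand setting, genes that overlap a gene on the other strand are uncertain, as are members of families with near-identical copies such as histones.

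The authors deposited one table of log2 CPM, the reads of a gene relative to the size of its library, with a small prior count added, for 17636 genes and 4 libraries. The unit was read from the values. In each column, 2 to the power of the value minus the lowest value fell on whole multiples of a single step for 100% of genes, within 0.001 of a read, so the reads behind each gene and the effective library size were recovered. The effective sizes were 16747958 and 16790810 reads for the untreated libraries and 13527069 and 10541396 for the cisplatin libraries, which are 0.942, 1.02, 0.981 and 1.09 times the reads listed. The 2 mitochondrial ribosomal RNA genes took 23.4% and 20.1% of the listed reads in untreated replicates 1 and 2, and 24.4% and 19.3% in cisplatin replicates 1 and 2. Printed CPM values are recovered reads scaled by the effective size, with no prior. Low genes were missing from the deposited table, in which the lowest total of a gene was 31 reads and each gene reached at least 0.949 CPM in 2 libraries, so no fit without a filter was possible.

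Groups were taken from the sample titles. The test was limma 3.58.1 in R 4.3.3, a linear model on the deposited log2 values with treatment as its only term, moderated variances with a trend on expression, and Benjamini-Hochberg adjustment over 17636 genes at 0.05. The test fixed before the data were examined was a count model, with log2(value + 1) for normalized values. Since the values were already on a log2 scale, they were used as they stood, and log2(CPM + 1) was run as an alternative chosen after seeing the data. Fold changes include the authors' prior count, which understates changes of low genes. An SE is that of limma's moderated test.

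Before the data were examined, 41 gene lists were fixed that cover responses to a crosslinking drug, the tumour model and the other cell types of a dissociated lung. Lists with at least 5 tested members were tested with limma's camera, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 41 lists. The same test with an estimated correlation is given beside each call. Members were also counted after adjustment over the list alone. The rule for named genes, also fixed then, took Kras, Trp53, Cdkn1a and Mdm2, then up to 12 genes per direction with the largest change among those past the threshold with a mean of at least 3 on the log2 CPM scale and separated libraries, and up to 4 members per list with the smallest p. The part on the largest changes gave no gene, since none passed.

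Gene positions, spans, exonic lengths and transcript GC content came from GENCODE annotation of GRCm38, which is the build mm10. Gene names were matched through current and older symbols, and 17404 of 17636 genes, or 98.7%, had a gene model.

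Scripts were tested on simulated reads drawn for the 17636 genes from the replicate means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. The reads were recovered for 100% of values. The test without a replicate term called 0 of the changed genes at either size, while its median absolute log2 fold changes were 1.02 and 1.98. Camera with the preset correlation called the simulated changed list and 0 of 20 unchanged lists. Those unchanged lists held random genes with reads drawn independently. They therefore do not test false calls among lists whose members move together. With an estimated correlation the simulated changed list had an adjusted p of 0.0521 and was not called.

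The alternatives were median-of-ratios scaling, read totals alone, a filter at a mean CPM of 5, voom, robust variance shrinkage, pseudocounts of 0.1, 1 and 5, the replicate number as a block, and each library left out in turn. For lists they were the estimated correlation, fry, the block, the block with an estimated correlation, the filter at a mean CPM of 5 and the left-out libraries.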

Results

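Spheres grown from mouse lung tumours were profiled by RNA sequencing with and without cisplatin, a platinum drug that crosslinks DNA. The tumours carried an activated Kras allele and a deleted Trp53, the gene of the tumour suppressor p53. Cells of the dissociated lungs, depleted of cells positive for CD45 (blood leukocytes), CD31 (endothelium) and TER119 (erythroid cells), formed spheres in Matrigel. On day 4 the spheres received 10 µM cisplatin or the PBS vehicle, and RNA was taken 36 h later, on day 6. There were 2 untreated and 2 cisplatin libraries, each with values for 17636 genes. The reads behind the listed genes numbered 17788994 and 16467973 in untreated replicates 1 and 2, and 13794539 and 9639304 in cisplatin replicates 1 and 2. The number of genes listed at 0 was 5 in each untreated library, 13 in cisplatin replicate 1 and 157 in cisplatin replicate 2. Nothing in the labels says that the replicates came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

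The comparison asked which transcripts differ in tumour spheres after 36 h of cisplatin. Genes of cell division and DNA replication were higher in the treated spheres, and markers of alveolar type 2 cells, fibroblasts, the unfolded protein response and hypoxia were lower. The median member of the mitosis and G2 list was higher by 1.04 on the log2 scale, and that of the alveolar type 2 list was at -1.06. Of 41 gene lists, 7 rose and 10 fell in limma's camera test with a preset correlation between genes. No list passed with an estimated correlation, where the lowest adjusted p was 0.465. A simulated list of changed genes also missed in that camera test (adjusted p = 0.0521). Missing there therefore does not show that a list was unchanged. No single gene of 17636 passed limma's test with treatment as its only term, at an adjusted p of 0.05. The lowest adjusted p was 0.108, and 1946 genes had an unadjusted p under 0.05, of which 777 were higher and 1169 lower with cisplatin. The voom form of limma on the recovered reads also called 0 genes, with 1917 under 0.05 unadjusted. On simulated libraries with the same replicate differences, the test called 0 of 100 genes changed 2-fold and 0 of 100 changed 4-fold. A count of 0 therefore does not show that single genes were alike. A fit that took the replicate number as a block called 2571 genes and is described with the processing below. Both cisplatin libraries lay on one side of both untreated libraries for 7549 genes, or 42.8%. If the 4 libraries were exchangeable, 33.3% would be so by chance. Replicate differences correlated between the groups (r = 0.685), so that value is not an exact reference.

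The genes of the tumour model were read first. Kras (chromosome 6, 145216699 to 145250239 in GRCm38) stood at 99.9 ± 5.13 CPM in untreated spheres and 91.3 ± 12.9 CPM with cisplatin (SD, n = 2), with a log2 fold change of -0.14 (SE 0.19, limma adjusted p = 0.825). Without cisplatin replicate 2 that log2 fold change was 0.01. Trp53 (chromosome 11, 69580359 to 69591873) gave 5.67 ± 0.0946 CPM untreated and 10.3 ± 1.83 CPM with cisplatin (SD, n = 2), a log2 fold change of 0.84 (SE 0.30, limma adjusted p = 0.382). Values per gene do not show which exons the reads came from, so they check neither the deletion nor the activated Kras allele. Cdkn1a, which encodes the cell cycle inhibitor p21, was at 83.1 ± 4.87 CPM against 106 ± 14.5 CPM (log2 fold change 0.35, limma adjusted p = 0.554). Mdm2, the ubiquitin ligase that targets p53, was at 49.5 ± 0.880 CPM against 67.8 ± 0.318 CPM (log2 fold change 0.45, limma adjusted p = 0.429).

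Mitosis and G2 genes rose as a list. All 36 tested members had a positive log2 fold change, and in 29 both cisplatin libraries exceeded both untreated ones (camera adjusted p = 2.62e-18, and adjusted p = 0.636 with an estimated correlation). None of the 36 passed over all genes, and 20 passed when adjusted over the list alone. Birc5, which encodes survivin, was at 10.8 ± 2.00 CPM untreated and 26.6 ± 6.03 CPM with cisplatin (SD, n = 2; log2 fold change 1.28, SE 0.28). The kinetochore gene Ndc80 had a log2 fold change of 1.25 (SE 0.30), Espl1, which encodes separase, 1.34 (SE 0.34), and the mitotic kinase gene Aurka 1.27 (SE 0.33).

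DNA replication and S phase genes rose likewise, with 34 of 38 members positive and a median log2 fold change of 0.76 (camera adjusted p = 5.16e-17, and adjusted p = 0.465 with an estimated correlation). Of the 38, 0 passed over all genes and 23 passed when adjusted over the list alone, each of them higher. Mcm3, a subunit of the replicative helicase (chromosome 1, 20802968 to 20820312), stood at 30.6 ± 0.983 CPM untreated and 86.8 ± 25.1 CPM with cisplatin (SD, n = 2; log2 fold change 1.47, SE 0.25). The helicase genes Mcm5 and Mcm6 had log2 fold changes of 1.43 (SE 0.27) and 1.12 (SE 0.22). Pole, the catalytic subunit of DNA polymerase epsilon, was at 11.3 ± 0.316 CPM against 26.4 ± 0.0137 CPM.

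DNA repair lists rose by smaller amounts. Whether these rises are separate from those of the mitosis and S phase lists was not tested. Homologous recombination genes had a median log2 fold change of 0.35, with 17 of 23 members positive (camera adjusted p = 0.00036, and adjusted p = 0.465 with an estimated correlation), and 1 member passed when adjusted over the list alone. Rad51, the recombinase that pairs homologous strands, was at 10.4 ± 1.24 CPM untreated and 27.0 ± 0.664 CPM with cisplatin (SD, n = 2; log2 fold change 1.37, SE 0.24). Brca1 had a log2 fold change of 1.00 (SE 0.28) and Rad54l 1.13 (SE 0.33). Nucleotide excision and Fanconi crosslink repair genes had a median of 0.19, with 20 of 28 positive (camera adjusted p = 0.0106, and adjusted p = 0.465 with an estimated correlation), and none passed when adjusted over the list alone. Ube2t, the ubiquitin-conjugating enzyme of the Fanconi pathway, had a log2 fold change of 1.04 (SE 0.30) and the helicase gene Ercc2 0.73 (SE 0.25). Without cisplatin replicate 1 the adjusted p of this repair list was 0.053.

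p53 target genes rose as a list, with a median log2 fold change of 0.35 and 29 of 39 members positive (camera adjusted p = 0.000172, and adjusted p = 0.465 with an estimated correlation). The 4 members with the smallest p were Trp53inp1 (log2 fold change 1.06, SE 0.22), Ckap2 (1.03, SE 0.22), Pidd1 (1.61, SE 0.40) and Gtse1 (1.10, SE 0.35). Ckap2 and Gtse1 encode microtubule-associated proteins of dividing cells, and Trp53inp1 and Pidd1 encode proteins of the p53 stress response. The other 10 of the 39 members were negative. Since the tumours carried a deleted Trp53 and some members belong to dividing cells, the rise does not show p53 activity. Over all genes 0 of the 39 passed, and 2 passed when adjusted over the list alone.

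Ribosome biogenesis genes rose, with a median log2 fold change of 0.40 and 28 of 31 members positive (camera adjusted p = 1.39e-06, and adjusted p = 0.465 with an estimated correlation). The nucleolar genes Nop2 and Nop56 were at 46.8 ± 0.0419 and 65.2 ± 0.515 CPM untreated, and at 90.7 ± 2.64 and 125 ± 18.7 CPM with cisplatin (SD, n = 2). They had log2 fold changes of 0.95 (SE 0.18) and 0.93 (SE 0.19), and 2 members passed when adjusted over the list alone. The 1507 protein-coding genes with a genomic span of up to 5 kb had a median log2 fold change of 0.11. Cytosolic ribosomal protein genes, with a median span of 3.47 kb, rose by a median of 0.12, near that of these short genes. Whether short span accounts for the rise of this list was not tested. Of its members, 50 of 60 were positive (camera adjusted p = 0.0127, and adjusted p = 0.844 with an estimated correlation). That call was lost without untreated replicate 1 (adjusted p = 0.467) and without cisplatin replicate 2 (adjusted p = 0.504).

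**Figure D1:**
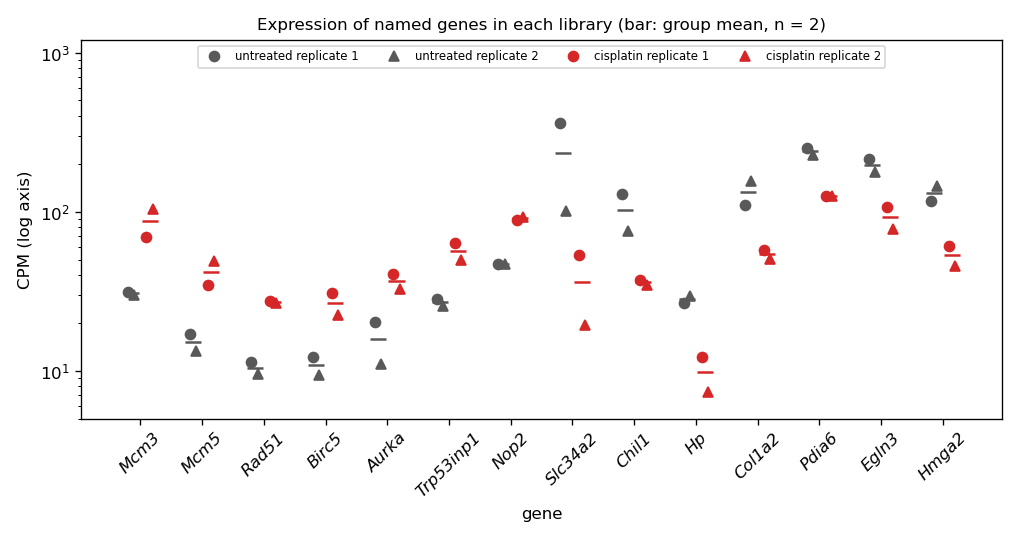
CPM on a log axis for 14 named genes in each of the 4 libraries, with untreated libraries in grey, cisplatin libraries in red and a bar at each group mean (n = 2). Mcm3 lies near 30.6 CPM untreated and 86.8 CPM with cisplatin, and Pdia6 near 239 and 126 CPM.

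Markers of alveolar type 2 cells, the surfactant-producing cells of the lung, fell as a list. In 19 of 20 members the log2 fold change was negative (camera adjusted p = 1.39e-06, and adjusted p = 0.640 with an estimated correlation), and 1 member passed when adjusted over the list alone. Chil1, a chitinase-like protein gene (chromosome 1, 134182176 to 134190181), was at 103 ± 38.3 CPM untreated and 35.9 ± 1.88 CPM with cisplatin (SD, n = 2; log2 fold change -1.46, SE 0.28). Slc34a2, a phosphate transporter gene, was at 232 ± 185 CPM against 36.2 ± 23.8 CPM (log2 fold change -2.58, SE 0.66). Lamp3 and Cxcl15 had log2 fold changes of -1.77 (SE 0.56) and -1.88 (SE 0.65). Leaving out 1 library moved the size of the last 3. Between libraries of the same number, the log2 fold change of Slc34a2 varied less, at -2.77 for number 1 and -2.38 for number 2. The log2 fold change of Slc34a2 was -1.66 without untreated replicate 1, -3.49 without untreated replicate 2, -3.30 without cisplatin replicate 1 and -1.85 without cisplatin replicate 2. Over the same 4 fits, that of Lamp3 ran from -2.50 to -1.03 and that of Cxcl15 from -2.84 to -0.91, each lowest without untreated replicate 2 and highest without untreated replicate 1.

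Of the other airway and alveolar lists, the club and alveolar type 1 markers fell, while ciliated markers (median 0.06, camera adjusted p = 0.684) and basal markers (-0.15, adjusted p = 0.758) did not pass. Club and secretory airway markers had a median of -0.74, with 7 of 11 members negative (camera adjusted p = 0.0144, and adjusted p = 0.636 with an estimated correlation). Scgb1a1, a club marker chosen after its values were seen, hardly moved. It was at 159 CPM untreated and 162 CPM with cisplatin (log2 fold change 0.05). Hp, which encodes haptoglobin, was at 28.1 ± 1.97 CPM untreated and 9.80 ± 3.39 CPM with cisplatin (SD, n = 2; log2 fold change -1.55, SE 0.30), and the mucin gene Muc5b had a log2 fold change of -1.40 (SE 0.44). Alveolar type 1 markers had a median of -0.49, with 15 of 16 members negative (camera adjusted p = 0.00718, and adjusted p = 0.844 with an estimated correlation). Vegfa, an angiogenic growth factor gene that the hypoxia list also holds, had a log2 fold change of -0.94 (SE 0.19), and Pdpn, which encodes podoplanin, -0.91 (SE 0.24). Ager, a type 1 marker also chosen after its values were seen, was at 203 CPM untreated and 198 CPM with cisplatin (log2 fold change -0.12, SE 0.62). In each of these lists 1 member passed when adjusted over the list alone. The club call was lost without untreated replicate 1 (adjusted p = 0.166) and over genes with a mean CPM of at least 5 (adjusted p = 0.0669). The alveolar type 1 call was lost without untreated replicate 1, and without cisplatin replicate 2 the direction turned. Between libraries of the same number the alveolar type 1 median was negative, at -0.23 for number 1 and -0.77 for number 2.

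Of the lists for non-epithelial cells, fibroblast, smooth muscle and macrophage markers passed the camera test. Endothelial, mesothelial, lymphocyte and granulocyte, and erythroid markers did not (camera adjusted p = 0.718, 0.782, 0.782 and 0.736). Of the 18 endothelial members, 11 were positive. The endothelial list fell over genes with a mean CPM of at least 5 (camera adjusted p = 0.00388). That filter left only Flt1, Car4, Prox1, Esam and Calcrl and removed low members such as Pecam1 and Kdr, so it does not speak for the whole list. Fibroblast markers fell by a median of -0.58, with 18 of 23 members negative (camera adjusted p = 0.00036, and adjusted p = 0.465 with an estimated correlation), and 4 passed when adjusted over the list alone. The collagen gene Col1a2 was at 133 ± 32.5 CPM untreated and 53.8 ± 5.18 CPM with cisplatin (SD, n = 2; log2 fold change -1.28, SE 0.23). Col3a1 had a log2 fold change of -1.44 (SE 0.33) and Pdgfra, a growth factor receptor gene, -1.22 (SE 0.28). Smooth muscle and pericyte markers had a median of -0.40, with 9 of 13 negative (camera adjusted p = 0.0451, and adjusted p = 0.636 with an estimated correlation). The contractile genes Tagln and Acta2 had log2 fold changes of -1.12 (SE 0.35) and -0.98 (SE 0.38). Macrophage and monocyte markers had a median of -0.70, with 16 of 20 negative (camera adjusted p = 0.0201, and adjusted p = 0.823 with an estimated correlation). Marco, a scavenger receptor gene, was at 24.9 ± 21.8 CPM against 6.95 ± 7.21 CPM, and its log2 fold change of -2.01 became -3.32 without cisplatin replicate 2 and -0.70 without cisplatin replicate 1. The smooth muscle call was lost without untreated replicate 2, cisplatin replicate 1 or cisplatin replicate 2 (adjusted p = 0.245, 0.0862 and 0.0755). The macrophage call was lost without untreated replicate 2 and over genes with a mean CPM of at least 5 (camera adjusted p = 0.180). Without cisplatin replicate 1 its direction turned. Between libraries of the same number the macrophage median was negative, at -0.69 for number 1 and -0.33 for number 2.

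Unfolded protein response genes fell, with a median log2 fold change of -0.55 and 18 of 21 members negative (camera adjusted p = 3.67e-07, and adjusted p = 0.465 with an estimated correlation). Over all genes 0 passed, and 8 passed when adjusted over the list alone. Pdia6, a disulfide isomerase gene of the endoplasmic reticulum (chromosome 12, 17266545 to 17284770), was at 239 ± 15.6 CPM untreated and 126 ± 0.194 CPM with cisplatin (SD, n = 2; log2 fold change -0.93, SE 0.17). Pdia4 had a log2 fold change of -0.90 (SE 0.18), the transcription factor gene Xbp1 -0.80 (SE 0.17) and the chaperone gene Hsp90b1 -0.68 (SE 0.17).

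Hypoxia and glycolysis genes fell, with 26 of 28 members negative and a median of -0.46 (camera adjusted p = 3.71e-06, and adjusted p = 0.640 with an estimated correlation), and 3 passed when adjusted over the list alone. Egln3 and Egln1, which encode oxygen-sensing prolyl hydroxylases, had log2 fold changes of -1.09 (SE 0.22) and -0.81 (SE 0.18), and the glucose transporter gene Slc2a1 -0.61 (SE 0.17). Epithelial-mesenchymal transition genes fell by a median of -0.45, with 17 of 21 negative (camera adjusted p = 0.000851, and adjusted p = 0.636 with an estimated correlation), and 5 passed when adjusted over the list alone. Hmga2, a chromatin protein gene, was at 131 ± 19.4 CPM untreated and 53.2 ± 10.8 CPM with cisplatin (SD, n = 2; log2 fold change -1.30, SE 0.22), and Fn1, the fibronectin gene, had a log2 fold change of -1.45 (SE 0.34). Without cisplatin replicate 1 the adjusted p of that list was 0.252. NRF2 and glutathione genes, which handle oxidants and conjugate drugs, fell by a median of -0.24, with 22 of 30 negative (camera adjusted p = 0.0144, and adjusted p = 0.546 with an estimated correlation). Aox1, an aldehyde oxidase gene, had a log2 fold change of -1.20 (SE 0.30) and Me1, the malic enzyme gene, -0.67 (SE 0.22). Without cisplatin replicate 2 the adjusted p was 0.170. Fibroblast markers, described with the other cell types, had a median of -0.58 beside the -0.45 of the transition list.

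**Figure D2:**
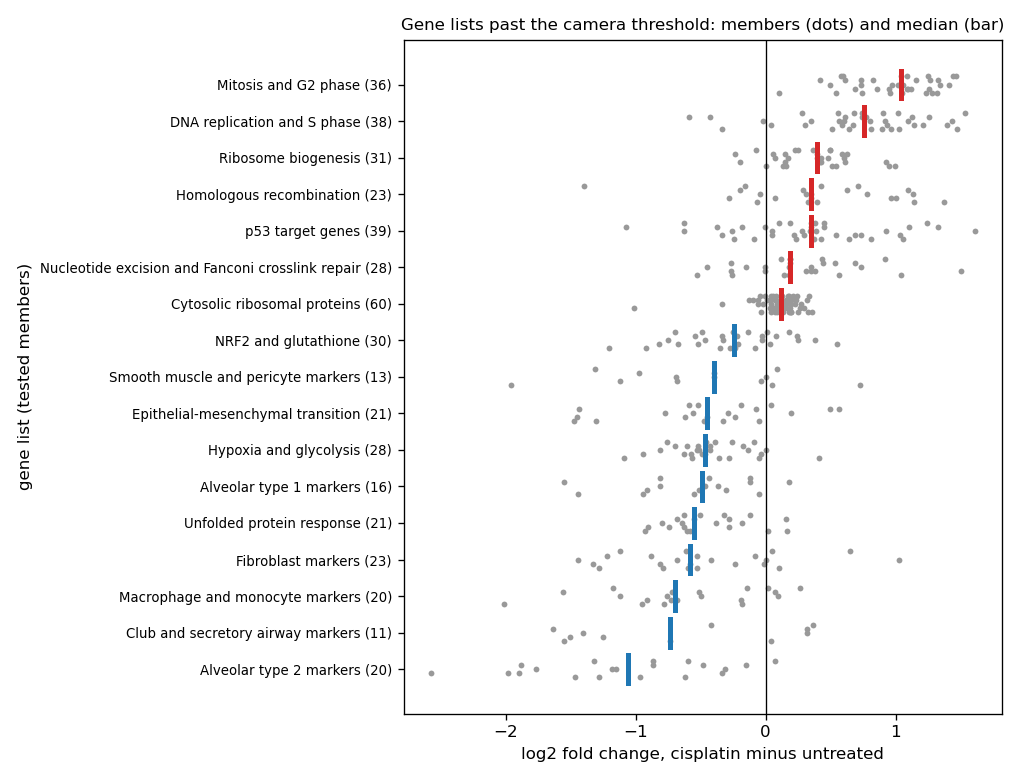
Log2 fold change of each tested member (grey dots) and the list median (bar, red for lists that rose and blue for lists that fell) for the 17 lists past the threshold, with cisplatin minus untreated on the x axis and the number of tested members after each name. The median of the mitosis list lies at 1.04 and that of the alveolar type 2 list at -1.06.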

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

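The fits with a pseudocount of 1, the filter on the list tests, and the fits that join the block with another setting were chosen after seeing the data. The count of 0 genes held in each of the 13 fits without the block, at lowest adjusted p from 0.0625 to 0.641, including those without 1 library, where the range was 0 to 0 and the lone sample is assumed to vary like the other group. With the replicate number as a block, limma called 2571 genes, 909 higher and 1662 lower. The labels do not say what the number marks, and with 2 pairs the data cannot settle it. The difference between replicates 1 and 2 correlated between the groups (r = 0.685 across 9457 genes, which are not independent replicates), and the order of the rows in the authors' table followed the blocked p (Spearman 0.996) more closely than the p without a block (0.957). The blocked fit has 1 residual degree of freedom, so its error comes almost wholly from the trend across genes. On the simulated libraries it called 88 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 9 of 197 calls false (4.57%), but those libraries were drawn with a replicate effect shared by both groups, so they do not test whether the numbers pair the samples. The paired count was 2544 with voom (963 higher, 1581 lower), 2645 with median-of-ratios scaling (890 and 1755), 2740 with read totals (1378 and 1362), 2656 at a mean CPM of 5 (983 and 1673) and 2564 with a pseudocount of 5 (917 and 1647). Read totals moved the share of higher calls from 35.4% to 50.3% and the median of all genes from -0.01 to 0.07. Of the lists, 17 were called, 0 with an estimated correlation with or without the block, 4 by fry, 19 with the block and 16 to 19 without 1 library. Over genes with a mean CPM of at least 5, 37 lists kept 5 members and 16 were called, with the interferon (adjusted p = 0.0419) and endothelial (0.00388) lists added, the club (0.0669) and macrophage (0.180) lists lost and the smooth muscle list too short to test. With the block, cholesterol synthesis, ERK and YAP lists were called and the smooth muscle list was not. In the fits without 1 library, 9 of the 17 lists were called in the same direction each time. Those that turned were macrophage markers without cisplatin replicate 1 (adjusted p = 0.998), and alveolar type 1 markers without cisplatin replicate 2 (0.769), where the lowest adjusted p without another library was 9.62e-06 and 1.65e-06. The log2 fold change of Kras ran from -0.28 without cisplatin replicate 1 to 0.0074 without cisplatin replicate 2. The cause of these changes was not tested. A fit without 1 library leaves the replicate numbers unbalanced between the groups, so differences between replicates 1 and 2 enter its estimates. For the 8 called lists not called in the same direction in each such fit, the median kept its sign between libraries of the same number. The values were deposited as log2 CPM and tested on that scale, so the planned edgeR test is not reported and the DESeq2 test was not run, although the recovered reads would allow a count model. An exploratory edgeR run was made on those reads while the row order was examined. Without the block, its likelihood ratio tests called genes and its quasi-likelihood test did not, and its counts are not given. The fit with no filter was not run, because the table came filtered. Depth limits low genes most in cisplatin replicate 2, with 9639304 listed reads.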

Other observations

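The tests of reduced transcription of long genes, of the epithelial share and of the surfactant genes were chosen after the results were seen. Among lists that did not pass camera, some members are given as values. Of the chemokine list, Cxcl10 was at 2.03 ± 0.678 CPM untreated and 8.96 ± 2.22 CPM with cisplatin (SD, n = 2; log2 fold change 2.08, SE 0.40, limma adjusted p = 0.191) and Cxcl16 at 47.4 ± 8.31 against 102 ± 2.35 CPM, while Lcn2, which encodes lipocalin, was at 79.5 ± 11.2 against 31.5 ± 13.3 CPM. The keratin gene Krt6a had a log2 fold change of 2.37 (SE 0.41) and Ivl, the involucrin gene, -1.15 (SE 0.33), both in the basal and squamous list. Of the secretory list of senescent cells, Igfbp3, Mmp10 and Mmp3 had log2 fold changes of -1.23, -1.44 and -1.46. The interferon-stimulated list had a median of 0.15 (camera adjusted p = 0.112), with Rsad2 at 1.21 and Mx1 at 1.01. Polr2a, the gene of the largest subunit of RNA polymerase II, chosen after its values were seen, was at 261 ± 44.5 CPM untreated and 704 ± 137 CPM with cisplatin (log2 fold change 1.43, SE 0.22, limma adjusted p = 0.137).

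The other lists that did not pass had medians of 0.40 for histones (adjusted p = 0.164), 0.01 for apoptosis regulators (0.578), -0.09 for antigen presentation (0.332), -0.03 for cytokines and chemokines (0.642), 0.11 for NF-kB feedback (0.164), -0.11 for senescent secretion (0.146), 0.08 for ATF4 targets (0.718) and -0.18 for metallothioneins and platinum transport (0.585). Heat shock genes had 0.08 (0.642), cholesterol synthesis -0.23 (0.0585), nuclear-encoded oxidative phosphorylation 0.05 (0.146), mitochondrially encoded transcripts -0.16 (0.420), ERK response -0.31 (0.0585), YAP targets -0.35 (0.0730), Wnt and Notch targets -0.30 (0.308) and stem cell markers -0.10 (0.332). Ciliated markers had 0.06 (0.684), basal -0.15 (0.758), simple epithelial -0.22 (0.146), mesothelial -0.17 (0.782), endothelial 0.13 (0.718), lymphocyte and granulocyte 0.36 (0.782) and erythroid -0.19 (0.736). The sign of the median and that of the camera test differed for cytokines, ATF4 targets, mesothelial and endothelial markers.

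Genes with a long genomic span had lower values with cisplatin. Over 14944 protein-coding genes, which are not independent replicates, the median log2 fold change was 0.11 for spans of 10 to 25 kb, -0.18 for 50 to 100 kb, -0.60 for 200 to 400 kb and -0.35 above 400 kb. With exonic length, GC content and expression in the model the slope was -0.38 per 10-fold span, which argues against those properties. Its SE was 0.02, from leaving out each of 20 chromosomes. In that model the slope was -0.0086 (SE 0.0149) between the untreated libraries and 0.08 (SE 0.02) between the cisplatin libraries. Without those terms it was 0.16 between the cisplatin libraries, beside -0.25 for cisplatin minus untreated in the libraries numbered 1. The flat untreated slope argues against variation between libraries, but 1 pair per group cannot exclude it. The SEs cover spread over genes only. Reduced transcription of long genes under cisplatin is a hypothesis that stays open. The slopes of -0.34 and -0.43 for the libraries numbered 1 and 2 are parts of the slope that raised it. Class medians fell from -0.03 at 25 to 50 kb to -0.60 at 200 to 400 kb, as the test first asked. The class above 400 kb breaks that trend, and the condition on it was added after its value was seen. A change in the makeup of cells also stays open and was not tested. Cpq, a gene of 511 kb chosen after its values were seen, was at 25.5 ± 2.10 CPM untreated and 2.87 ± 0.503 CPM with cisplatin.

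Mitosis and S phase genes together had a median log2 fold change of 0.91 over 74 genes. Short span does not account for this, since the highest median of 10000 random lists matched on span and expression was 0.26. Scaling does not either, since the median was 0.90 with median-of-ratios scaling and 0.99 with read totals. A higher share of epithelial cells would raise epithelial genes by about the same amount, and their median lay 1.13 lower (SE 0.10, over genes). A higher share of dividing cells after cisplatin, a shift in the phase in which cells stopped, and loss of non-dividing cells may each give this pattern, and were not told from one another.

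Markers of alveolar type 2 cells had a median of -1.06, below the lowest median of 10000 matched random lists, which was -0.33, so span does not account for it. Fewer such cells would lower genes made by these cells alone by the same amount. Sftpc, Sftpa1, Sftpb and Sftpd, surfactant genes chosen after their values were seen, had log2 fold changes that lay between -3.28 and -0.26 without 1 library, and Sftpc, Sftpb and Sftpd moved together from library to library. The range over the 4 was 0.83, between Sftpc and Sftpd, and the SE of that difference taken within libraries was 0.11, on 2 residual degrees of freedom and for the widest of 6 pairs, of which 2 lay beyond 2 SE. Other cells may also make some of these genes, so unequal falls do not decide, and fewer such cells and lower expression in them cannot be told apart.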
